A study of Homo sapiens with 6 samples.

How the data were processed

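RNA from human mast cells was measured on 6 two-colour spotted cDNA arrays. Per the labels, each array carried mast cell RNA in the Cy5 channel and a reference made from cell lines in the Cy3 channel. The labels give 2 batches of cells, S7 and S8, each sampled at 0, 1 and 2 h, so that every time point has 2 arrays and every batch 3. They describe the experiment as a stimulation of mast cells and name no stimulus, dose, donor or culture method. Whether the 2 batches came from separate donors or cultures is not stated, so p-values measure the spread between these samples, part of which may be technical.

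The deposited values are 1 log ratio per spot and array, and they were used as log2 values. The authors' log base, background correction, spot filter, normalization and ratio direction are not given in the sources used here. Base 10 was excluded by the range of the values, and base 2 was taken as the usual base of such tables, so every fold depends on that reading. The medians of the 6 arrays were -0.01, -0.09 and -0.05 in batch S7 (0, 1 and 2 h) and 0.01, 0.01 and 0.04 in batch S8. All lay within 0.1 log2 of their mean, and by the rule fixed for this case the deposited values were used without further centring.

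The direction, mast cell over reference, is likely rather than stated. It rests on the dyes in the labels and on gene lists set against 10000 random lists of the same size. The 12 measured cell cycle genes, which dividing cell lines express highly, averaged between -2.36 and -1.68 on the 6 arrays, below all 10000 random lists. The 6 measured B cell and plasma cell markers averaged between -1.98 and -1.31. The 4 measured mast cell genes (KIT, FCER1A, MITF and LYN) averaged between 0.19 and 1.07, at percentiles from 78.9 to 98.4 of random lists, which is weak by itself. The check fixed beforehand named this list alone and asked for a mean far above 0 on every array. It was not met on the 1 h array of batch S7 (0.19), and the cell cycle and B cell lists were not part of it. With the sign turned, every rise given here would be a fall. All pairs of arrays correlated positively over spots (r from 0.565 to 0.847), and no 2 arrays held the same values.

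The array has 18432 spots. Spots for Y-linked genes or XIST (20) were left out. Of the 18412 others, the platform annotation named 5336 with 1 gene symbol, 260 with several and 12816 with none. Of the 5336, 5328 were matched to the current gene table (GRCh38.p14, used for names only) through their Entrez number, and the other 8 kept the annotation's symbol. A spot without a symbol is unnamed here, not without a gene. The number of spots without a value was 979 on the 1 h array of batch S7 and between 133 and 265 on the other 5 arrays. Spots with a value on all 6 arrays (16816) were kept, and clones of 1 symbol were averaged. This gave 14584 features, of which 2670 were named genes and 11914 unnamed clones. Of the named genes, 1428 had 1 clone and 1242 had 2 or more. The median SD of the 2 h change across clones of a gene was 0.250 log2, and the clones of 32 genes spanned over 2 log2 units.

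Time points were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with a mean for each time point over all 6 arrays and no batch term, and an adjusted p (Benjamini-Hochberg) under 0.05. The 2 batches were compared in a model with time and batch. Because the labels tie the arrays of 1 batch together, the time points were also compared with batch as a block. Deviations of same-batch arrays from the time means correlated at 0.496, 0.529 and 0.472 for the 3 pairs of times, so the batch numbers pair the arrays. The number of arrays limits the precision of every value, with 3 residual degrees of freedom without the block and 2 with it.

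In simulated arrays made from the real means, batch differences and spreads, 50 features of each of 4 sizes were changed at 2 h among 14584. Without the block the fit recovered 0 of 50 features changed 2-fold, 12 of 50 changed 4-fold, 35 of 50 changed 8-fold and 44 of 50 changed 16-fold, with 0 false calls. With the block it recovered 14, 48, 49 and 48 of 50, with 14 false calls. Most changes of 4-fold or less were therefore out of reach without the block.

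Lists of genes (27), fixed with the designs and the alternatives before the data were examined, cover early response genes, secreted factors, signalling, mast cell genes, metabolism and markers of other cell types. Lists with 5 or more measured members (14) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 42 tests, and again with an estimated correlation and with fry. With an estimated correlation camera has only the residual degrees of freedom, 3 without the block and 2 with it, which lowers its power. No member was measured for the lists of oxidative phosphorylation, eosinophil and basophil, megakaryocyte and platelet, and epithelial genes.

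The genes named were set by a rule. For 1 h and for 2 h against 0 h it took, among genes that passed and moved the same way in both batches, the 14 largest rises and the 8 largest falls. For 2 h against 1 h and for the batches it took 6 and 6. Open places went to genes that did not pass but changed by at least 1 log2 unit the same way in both batches, ranked by the smaller change. Up to 4 members of each list with the largest change at 2 h were added, and KIT, FCER1A, TPSB2 and CPA3 where measured; of these 4, KIT and FCER1A were.

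Alternatives covered median centring, quantile and scale normalization, a looser filter on missing values, each clone on its own, robust and trended variance estimates, a threshold of 0.10, a filter on range, the block, fits on the 4 arrays compared and leaving out each array. No genome came with this series, so no position is given. The fit on batch as a block without the 1 h array of batch S7, which had the most spots without a value, was added after the values had been seen.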

Results

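Gene expression was followed in human mast cells, the tissue-resident cells that store histamine and proteases in granules and release them on activation, at 0, 1 and 2 h of a stimulation that the labels do not specify. Each of the 2 batches of cells, S7 and S8, was measured once at each time on a two-colour array against a common reference of cell lines. A value is the log2 ratio of mast cell over reference, with the log base and the direction read as described for the processing. Between 17433 and 18279 spots per array had a value, and 2670 named genes and 11914 unnamed clones had one on all 6 arrays.

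The comparison of 1 h with 0 h asks which transcripts moved early after stimulation. Named genes that passed the test all rose. NR4A3 (Entrez Gene 8013), an orphan nuclear receptor of the immediate early class, had the largest rise, 26.1-fold (log2 change 4.70 ± 0.31, SD over batches, n = 2, adjusted p = 0.0188), with 4 clones that changed by 2.78 to 6.78 log2 units. NFKBID (84807), a nuclear regulator of NF-kappaB, rose 22.5-fold, from -0.30 to 3.53 in batch S7 and from -1.15 to 4.01 in batch S8. ITGA2 (3673), the collagen-binding integrin alpha-2, rose 20.8-fold, and MIR155HG (114614), the host transcript of the microRNA miR-155, rose 17.5-fold on the mean of 4 clones. IL3 (3562), a cytokine that acts on mast cells and basophils, rose 11.2-fold. Its 2 clones disagreed, with log2 changes of -0.21 and 7.18.

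The other 4 genes that passed were SMARCA2, a chromatin remodelling ATPase, with a 13.0-fold rise, IER3 (8.48-fold), ZFP36L2, which binds AU-rich messages (8.17-fold), and the clock gene PER3 (5.69-fold). Of the genes that passed, NFKBID, ITGA2, SMARCA2, IER3 and PER3 each rested on 1 clone. CCL4, a chemokine, had the highest mean change, 5.49 log2 units, on 1 clone. But it changed by 3.69 in batch S7 and by 7.30 in batch S8, from levels at 0 h of 0.62 and -4.52. CCL4 did not pass (adjusted p = 0.297, and 0.0985 with batch as a block). KPNA5 (3.61), ZNF598 (2.86), PELI1 (2.60) and UNC79 (2.53) rose only in the fit with batch as a block (adjusted p from 0.0169 to 0.0294). In that fit the GTP-binding GEM (2.82, on 2 clones that changed by 0.85 and 4.78), DTL, a substrate receptor of a ubiquitin ligase (2.45), and TASL, an adaptor of endosomal Toll-like receptors (2.00), rose at 1 h as well (0.0251 to 0.0397).

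Falls were fewer among the calls, although at an unadjusted p under 0.05 only 776 of 1705 features were higher at 1 h. With batch as a block, 4 of the genes named for a fall fell at 1 h, namely the zinc finger genes ZNF180 (-2.86 ± 0.33, SD over batches, n = 2), ZNF507 (-2.18) and ZNF592 (-1.74), and MOB3A (-1.81). Without the block their adjusted p lay between 0.0576 and 0.0635. Values that passed in neither fit were -2.39 for TXNIP, a thioredoxin inhibitor, -2.15 for BMF, a pro-apoptotic BH3-only gene, -1.74 for SEMA4D and -1.68 for ZBTB14.

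By limma, 42 of 14584 features changed at 1 h, 40 up and 2 down, and 9 of them were named genes. With batch as a block the count was 199, 169 up and 30 down, and it held all 42. With 1 array left out, which also lowers the power of the test, the calls numbered 18 (without the 1 h array of batch S7), 1 (without that of batch S8) or 0, while the log2 change of NR4A3 stayed between 4.46 and 4.95 and that of SMARCA2 between 3.54 and 3.87. Those fits had no block, and not all of their calls were among the 42. Quantile normalization, also without the block, gave 0 calls, median centring gave 77, and scale normalization gave 11, of which 9 were higher.

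**Figure D1:**
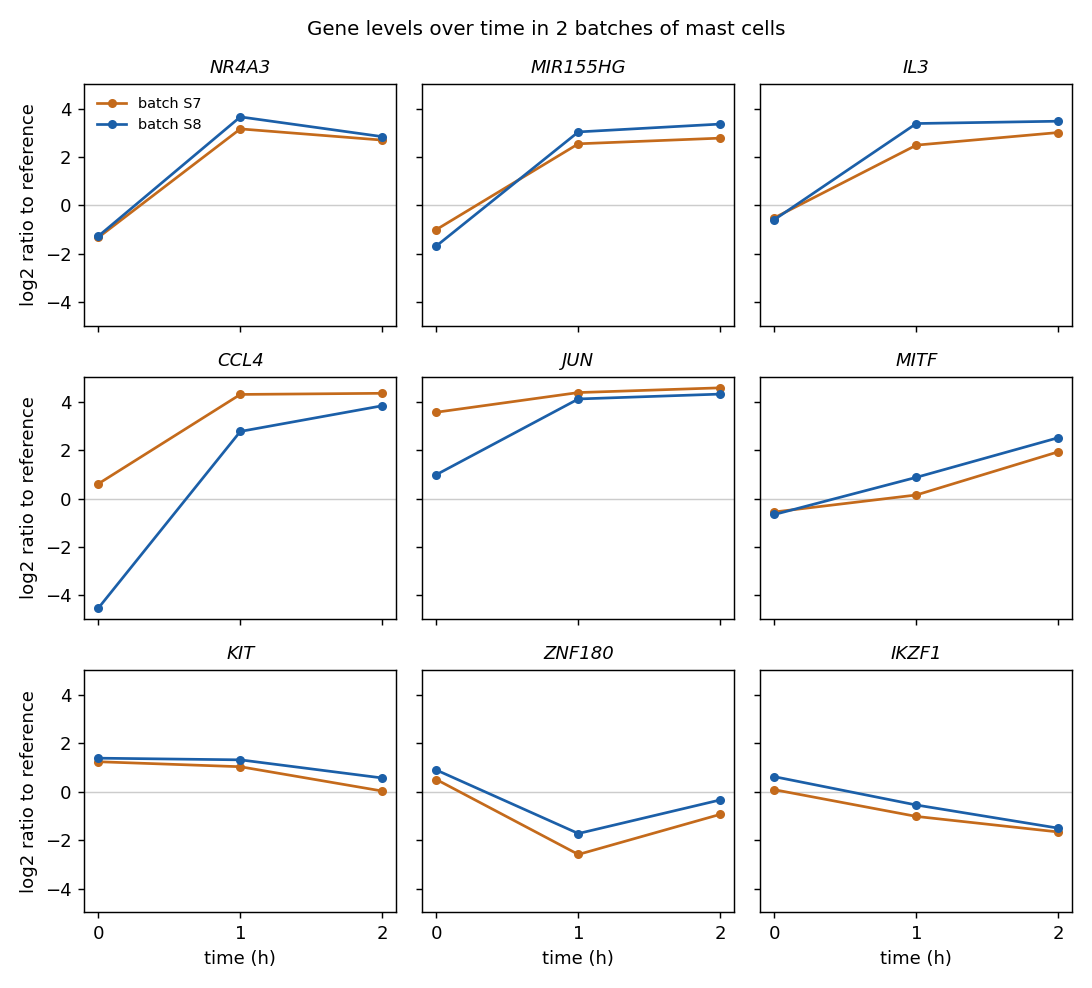
Log2 ratio to the reference (y axis) against time in hours (x axis) for 9 genes, 1 point per array, with a line joining the 3 arrays of each batch (batch S7 and batch S8). NR4A3, MIR155HG and IL3 rose by over 3 log2 units in both batches by 1 h, CCL4 and JUN started higher in batch S7 at 0 h, and ZNF180 was lowest at 1 h.

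Among the gene lists, early response genes moved most at 1 h. Of 13 measured immediate early transcription factors and regulators, 3 rose over all features tested (NR4A3, IER3 and ZFP36L2), 6 rose adjusted over the list alone, and 12 were higher in both batches. EGR3 (1.47) rose only with batch as a block (adjusted p = 0.0498). Camera put the list above other genes (adjusted p = 2.9e-10), and adjusted p = 0.358 with an estimated correlation. JUN, an AP-1 subunit, changed by 0.81 in batch S7 and 3.13 in batch S8 and did not pass (adjusted p = 0.431). Its level at 0 h was 3.57 in batch S7 against 0.99 in batch S8.

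Secreted factors were mixed. Of 20 measured cytokines and growth factors, 1 rose over all features (IL3) and 5 adjusted over the list alone. Camera's adjusted p for the list was 9.3e-04, and adjusted p = 0.358 with an estimated correlation. IL1A (2.58) and LIF (2.59) rose with batch as a block (adjusted p = 0.0207 and 0.0311), IL1A on 2 clones that changed by 0.19 and 4.98. IL5, an eosinophil growth factor, changed by 1.45 without passing. Of 7 chemokines, 0 passed by limma, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. With batch as a block 0 passed over all features and 1 rose over the list alone, and camera called the chemokine list only there (adjusted p = 0.0260, and adjusted p = 0.670 with an estimated correlation, against 0.143 without the block). The level of the chemokine CCL20 at 0 h was 3.75 in batch S7 and -0.57 in batch S8. The monocyte markers CD86 (1.27 and -1.21) and CSF1R (1.74 and -0.20) were apart in the same direction at 0 h.

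Of 12 measured NF-kappaB pathway genes and targets, 0 passed by limma over all features at 1 h, 4 at an unadjusted p under 0.05, and 4 rose adjusted over the list alone. Camera's adjusted p was 5.4e-05, and adjusted p = 0.358 with an estimated correlation. CD83, a maturation marker of antigen-presenting cells, changed by 2.62 on the mean of 7 clones and did not pass (adjusted p = 0.161). Of 10 signal feedback inhibitors, 1 rose adjusted over the list alone. RGS1, a brake on G protein signalling, rose with batch as a block (2.73, adjusted p = 0.0353), and the list was not called (adjusted p = 0.0535).

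At 2 h the comparison with 0 h asks which changes were present at the last time point. It shares its 0 h arrays with the comparison at 1 h, so calls in common are partly shared chance. MIR155HG had the largest rise of the genes that passed, 21.2-fold (log2 change 4.41 ± 0.89, SD over batches, n = 2, adjusted p = 0.0408). ITGA2 rose 17.5-fold, NR4A3 16.7-fold (clones from 2.31 to 6.10 log2 units), NFKBID 15.4-fold, IL3 13.9-fold, SMARCA2 9.58-fold and IER3 8.70-fold. The 2 IL3 clones again disagreed, with log2 changes of -0.14 and 7.72. KPNA5 (4.31), PELI1 (3.30), ZNF598 (3.23), DTL (3.07), MITF (2.83) and GEM (2.70, with clones at 0.78 and 4.62) rose with batch as a block, with adjusted p from 0.0122 to 0.0252. ZFP36L2 (2.29), PER3 (2.21), UNC79 (1.65) and PCGF5 (1.52) rose in that fit too, with adjusted p from 0.0252 to 0.0448. CCL4 changed by 3.74 in batch S7 and 8.36 in batch S8 and did not pass (adjusted p = 0.256, and 0.0782 with the block).

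MITF, the transcription factor that directs mast cell and melanocyte development, was the member of the mast cell list with the largest change at 2 h. It went from -0.55 to 1.94 in batch S7 and from -0.65 to 2.52 in batch S8, on 1 clone. KIT, the stem cell factor receptor on which mast cells depend, changed by -1.01 (adjusted p = 0.256, and 0.0965 with the block), and its 4 clones ranged from -2.06 to 0.37. FCER1A, the alpha chain of the high-affinity IgE receptor, changed by 0.10. LYN, a kinase that starts IgE receptor signalling, changed by -1.63 at 1 h and -0.46 at 2 h and passed at neither. Over this list alone 1 of 4 measured members rose and 1 fell at 2 h.

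Genes that fell at 2 h with batch as a block were BMPR2, a BMP receptor (-1.97), IKZF1, the lymphoid transcription factor Ikaros (-1.94, with 11 clones between -3.39 and 0.17), TRIB2 (-1.89), CDK8, a Mediator kinase (-1.74), and MOB3A (-1.62). Their adjusted p lay between 0.0248 and 0.0474 with the block and between 0.0976 and 0.138 without it. Values that passed in neither fit were -2.13 for CLCN4, -2.00 for GFI1, -1.83 for ZBTB14 and -1.74 for HMGN3.

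By limma, 36 of 14584 features changed at 2 h, 34 up and 2 down, and 7 of them were named genes. With batch as a block 157 changed, 130 up and 27 down, and the 36 were among them. Leaving out any 1 of the 6 arrays, which lowers the power, gave 0 calls without the block, with the log2 change of MIR155HG between 4.07 and 4.74. Quantile normalization without the block also gave 0 calls, and median centring gave 56.

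**Figure D2:**
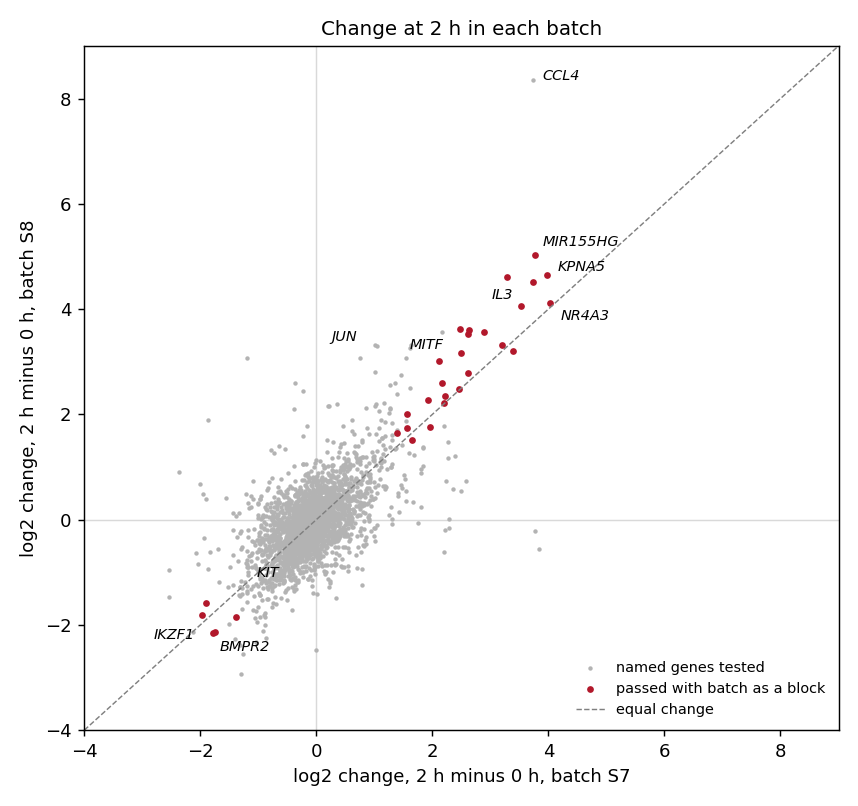
Log2 change from 0 h to 2 h in batch S7 (x axis) and in batch S8 (y axis), 1 point per named gene on all 6 arrays (2670 genes). Red points are the 30 genes that passed with batch as a block, and the dashed line marks equal change. Most red points on the upper right lie above the line, and CCL4 lies farthest from it.

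The lists at 2 h moved as follows. Of 13 immediate early genes, 2 rose over all features and 8 adjusted over the list alone, with camera's adjusted p = 9.5e-08, and adjusted p = 0.438 with an estimated correlation. Of 20 cytokines and growth factors, 1 rose over all features and 7 adjusted over the list alone, with an adjusted p = 2.4e-04, and adjusted p = 0.358 with an estimated correlation. IL1A rose with the block (2.48), and IL5 had a value of 1.72. Of 12 NF-kappaB genes, 0 passed by limma, 6 at an unadjusted p under 0.05, and 3 rose adjusted over the list alone (camera's adjusted p = 9.4e-05, and adjusted p = 0.358 with an estimated correlation). NFKB1 had a value of 1.69, CD44 1.49 and NFKBIE 1.25, and none of these 3 passed.

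IgE receptor signalling was the only 1 of the 14 tested lists that camera called lower than other genes at 2 h. Of its 16 measured members, 0 passed by limma, 3 were lower and 1 higher at an unadjusted p under 0.05, 0 passed adjusted over the list alone, and with the block 0 passed over all features and 2 fell over the list alone. The adjusted p of the list was 0.0197, and adjusted p = 0.358 with an estimated correlation. Its members with the largest values were VAV1 (-1.68), INPP5D (-1.01), BTK (-0.92) and PLCG2 (-0.75), none of which passed. INPP5D encodes SHIP1, an inhibitor of this pathway, while VAV1, BTK and PLCG2 transmit its signal.

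Other lists were not called at either time. They were survival and apoptosis (14 measured), cell cycle (12), chemokines at 2 h (7, adjusted p = 0.285), antigen presentation (7), T and NK cell markers (7), ribosomal proteins (6), B cell and plasma cell markers (6), interferon response (5) and stromal and endothelial markers (5). By limma 0 of their members passed over all features at either time. TNFRSF10A, a death receptor, had a value of -1.84 at 2 h and MCL1, an anti-apoptotic gene, 0.99. INSIG1, a regulator of cholesterol synthesis, changed by 0.75 in batch S7 and 3.07 in batch S8 at 2 h. None of these 3 passed. Over all 42 list tests, camera called 7 with the preset correlation and 0 with an estimated one, and fry called 3. The estimated correlation was -0.028 for cytokines and growth factors and -0.009 for IgE receptor signalling, under the preset 0.01. A higher correlation therefore does not account for the lost calls of these lists. It was 0.353 for the immediate early list and 0.055 for the NF-kappaB list.

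**Figure D3:**
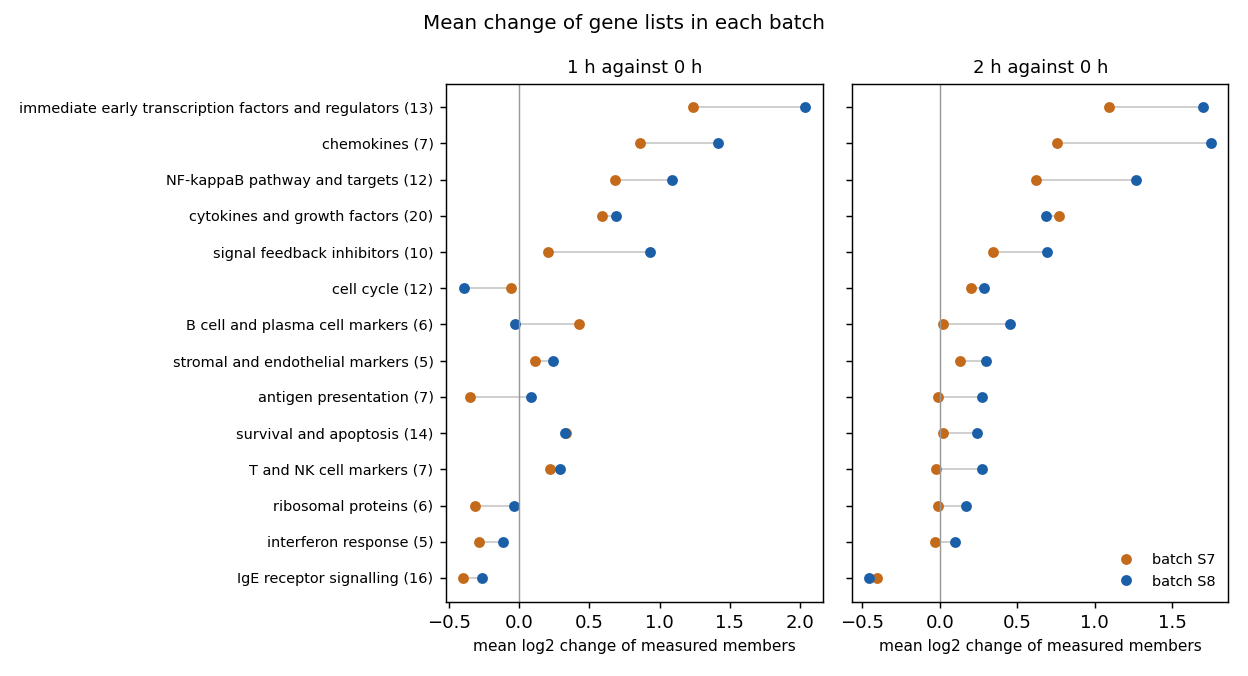
Mean log2 change (x axis) of each tested gene list (y axis, with the number of measured members in brackets) at 1 h and at 2 h against 0 h. Each point is the mean in 1 batch, and a grey line joins the 2 batches. The immediate early list averaged 1.24 in batch S7 and 2.04 in batch S8 at 1 h, and the IgE receptor signalling list was below 0 in both batches at both times.

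Between 1 h and 2 h no feature passed. Limma gave 0 calls with and without batch as a block, with 828 features at an unadjusted p under 0.05 without the block and 1584 with it. Among genes with a difference of at least 1 log2 unit in both batches, MITF was higher at 2 h by 1.71 (1.78 in batch S7 and 1.64 in batch S8), ZNF180 by 1.52, the replication licensing gene CDC6 by 1.63, PCGF5 by 1.48, FERMT1 by 2.13 and the antisense transcript TENM3-AS1 by 1.95. Values for genes lower at 2 h were -2.48 for MYNN, -1.65 for TASL, -1.63 for ASAP2, -1.53 for RASAL2 and -1.43 for FAM98A. The adjusted p of these 11 genes lay between 0.876 and 0.906 without the block. Which early changes grew or receded was not resolved by these arrays.

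The changes of the 2 batches were compared across features, which are not independent replicates. At 2 h, 570 features changed at least 2-fold the same way in both batches (387 up and 183 down) and 31 changed that much in opposite directions. At 1 h the numbers were 554 (374 up and 180 down) and 58. The correlation across features between batches was 0.569 at 2 h and 0.476 at 1 h. The 1 h change in 1 batch correlated with the 2 h change in the other batch at 0.456 and 0.477, with no array shared. For the change from 1 h to 2 h the correlation between batches was 0.161.

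The comparison of the 2 batches asks how far cells that carry the same label differed before and during the stimulation. The 3 arrays of a batch are samples of that batch at different times, not replicate batches. The SE and p of this comparison therefore measure how far the difference varied between time points, not how far batches or donors vary. The calls describe these 2 batches and cannot be extended to others. CYBB, the catalytic subunit of the phagocyte NADPH oxidase, was 28.2-fold lower in batch S8 (log2 difference -4.82, SE 0.15, 3 arrays per batch, adjusted p = 0.0018). The chemokine CCL20 was 28.0-fold lower, LILRB1, an inhibitory receptor of myeloid cells, 23.4-fold, the hyaluronan-binding TNFAIP6 16.5-fold, ACVR1 15.3-fold and lipoprotein lipase, LPL, 14.1-fold. Both measured monocyte and macrophage markers were lower in batch S8, CD86 by 6.36-fold (adjusted p = 0.0030) and CSF1R by 4.21-fold (adjusted p = 0.0046). Of 7 antigen presentation genes, 3 were lower in batch S8, among them HLA-DPA1 (3.50-fold). Of 5 stromal and endothelial markers, 2 were lower, fibronectin, FN1 (9.73-fold), and PECAM1 (log2 difference -2.32).

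None of the 4 measured mast cell genes passed between the batches. KIT differed by 0.32 (SE 0.16, adjusted p = 0.343), MITF by 0.40 (SE 0.22, adjusted p = 0.370), FCER1A by 0.23 (SE 0.26) and LYN by -0.33 (SE 0.30). Of 7 T and NK cell markers and 6 B cell markers 0 passed by limma in this comparison, and 0 adjusted over each list alone. PRKACB (4.04-fold), NMD3 (4.01-fold), NEO1 (3.36-fold), ASCC2, NLK and GTF2A1 had the largest differences of the genes that passed as higher in batch S8.

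In all, 522 features differed between the batches, 127 higher and 395 lower in batch S8, and 84 of them were named genes (19 higher and 65 lower). Leaving out 1 array gave between 189 and 291, of which 9 to 18 were higher in batch S8, again with lower power (the difference of NEO1 stayed between 1.49 and 1.90). The other array of that time point then no longer informs the batch difference. Leaving out either array of a time point therefore gave the same count (197 for 0 h, 291 for 1 h and 189 for 2 h). At an adjusted p under 0.10 the count was 1014, with 428 higher in batch S8. CYBB, CCL20, LILRB1, ACVR1 and LPL passed without any 1 time point. TNFAIP6, PRKACB and NMD3 passed in only 2 of the 6 fits with 1 array left out (highest limma adjusted p 0.074, 0.139 and 0.131). NEO1, ASCC2, NLK and GTF2A1 passed in none of the fits with 1 array left out, where lower power and dependence on 1 time point cannot be told apart.

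**Figure D4:**
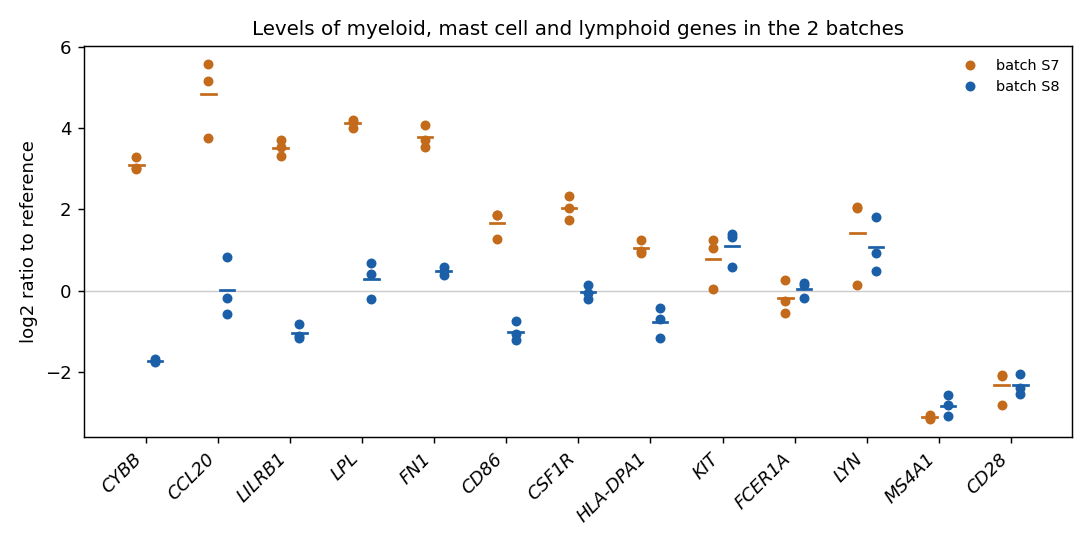
Log2 ratio to the reference (y axis) of 13 genes (x axis), 1 point per array, with a short bar at the mean of the 3 arrays of each batch. For CYBB, CCL20, LILRB1, LPL, FN1, CD86, CSF1R and HLA-DPA1 every array of batch S7 lies above every array of batch S8, while KIT, FCER1A, LYN, MS4A1 and CD28 overlap or lie close.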

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

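Each of 7 genes, among those taken by the rule for named genes, was flagged because its change from 0 h had one direction at 1 h and the other at 2 h in both batches. The mean changes also had to lie at least 1 log2 unit apart. FERMT1, TENM3-AS1, CDC6, ASAP2 and FAM98A had been taken by the rule for that same difference. The difference between the 2 times was tested by limma and did not pass for any of them. The flag therefore rests on direction and size alone, with 2 batches that share their 0 h arrays between the 2 changes. Mean log2 changes at 1 h and at 2 h are given in that order.

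FERMT1, an adhesion adaptor, had -1.29 and 0.84, and TENM3-AS1, an antisense transcript, -1.50 and 0.45. ASAP2, a regulator of ARF GTPases, had 0.16 and -1.46, and FAM98A 0.90 and -0.54. CDC6, which licenses replication, had -0.36 and 1.27, and the mitotic kinase AURKB -0.27 and 0.74. IRF4, a transcription factor of lymphoid and myeloid cells, had -0.50 and 0.65.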

How the results depend on the processing

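With 2 arrays per time point, calls at 1 h and 2 h against 0 h depended on the fit. Unless the block is named, the fits of the time points had no batch term, so differences between the batches stayed in their residual spread. The normalizations, the variance trend and the fits on the 4 arrays compared were not repeated with the block. Their counts therefore describe the fit without the block only. The genes taken by the rule for named genes and called in the main fit kept their sign with median centring, quantile normalization, the block and 1 array left out, while some lists that were not called turned direction. Calls at 1 h (42 in the main fit) numbered 77 with median centring, 0 with quantile and 11 with scale normalization (9 higher and 2 lower, against 40 and 2), 13 with a variance trend, 175 at an adjusted p under 0.10, 0 with only the 4 arrays compared and 0 to 18 with 1 array left out. Calls at 2 h (36) numbered 56 with median centring, 0 with quantile normalization, 11 with at least 4 of 6 values, 56 for each clone on its own, 5 with a variance trend, 128 at an adjusted p under 0.10, 0 with the 4 arrays compared and 0 to 0 with 1 array left out. The fits on fewer arrays have fewer residual degrees of freedom; for the other changes the cause was not tested.

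With batch as a block the counts were 199 at 1 h and 157 at 2 h, and 0 for 2 h against 1 h. Without the 1 h array of batch S7 they were 131 and 184 with the block. Other settings gave 39 to 57 calls at 1 h and 24 to 42 at 2 h. For 2 h against 1 h (0), leaving out 1 array gave 0 to 1. The batch comparison (522) gave 1014 at an adjusted p under 0.10 (428 higher in batch S8, against 127 of 522). It gave 189 to 291 with 1 array, and in effect its time point, left out (9 to 18 higher) and 416 to 677 otherwise. The list tests (7 called of 42) gave 0 with an estimated correlation, 3 with fry, 8 with the block and 6 to 11 with 1 array left out. Among the genes taken by the rule and the lists tested, the block changed no call but those given beside the results. Over all genes with a symbol it called 37 against 9 at 1 h and 30 against 7 at 2 h.

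Features changed at least 2-fold the same way in both batches numbered 1621 at 1.5-fold and 199 at 3-fold for 2 h (570), and 1558 and 218 for 1 h (554). The correlation of the 1 h change in batch S8 with the 2 h change in batch S7 was 0.372 by rank against 0.477; the others stayed within 0.1. Signal over background was not in the table, so limits from weak spots could not be examined.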

Other observations

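The 4 genes of this paragraph were picked after the values were seen, and they passed only with batch as a block. KDM6B, a histone demethylase, rose by 2.08 log2 units at 1 h and 1.79 at 2 h (means of 2 batches), STARD4, a sterol carrier, by 2.04 and 2.57, and ARID5B, a chromatin cofactor, by 1.98 and 1.58, with block adjusted p from 0.0232 to 0.0456. MAP3K8, a kinase upstream of NF-kappaB and ERK, rose at 1 h (3.06, block adjusted p = 0.0405) and had a value of 2.87 at 2 h that did not pass (0.0507).

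Tests of the split by batch and of 3 further patterns follow. Chosen only after the result was seen were the test of the T and NK and B cell lists, the SD test and the split of the macrophage genes by known expression in mast cells. For the batch comparison, the 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10, the real one, gave 522 calls, with 0 the highest of the others. Only 4 of the 10, the real one among them, part the arrays of every time point. The rest part only 1 time point, so only its arrays inform their difference. Every split but the real one also leaves the difference between the batches in the residual spread. Counts near 0 were therefore likely beforehand, and the splits are too few for a share under 0.05. This test cannot decide whether the calls arose by chance.

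Genes of macrophages were higher in batch S7, which cells of the monocyte and macrophage lineage in that batch may account for. Of 60 further macrophage genes, 13 were measured, and their median difference was 1.95, above all 10000 random lists, with 7 that passed as higher in batch S7 (among them IL10RA, LAIR1, AIF1 and FCGR2B) and 0 as lower; TYROBP differed by 0.15, and CCR2 and TNFRSF1B were lower in batch S7 at all 3 times. The 6 that mast cells also express had a median of 1.39 and the other 7 a median of 1.95, and myeloid transcription within mast cells was not separated from other cells. A lower share of mast cells would raise the markers of every other type present alike. The T and NK and B cell medians were -0.12 and -0.20, and 0.09 and 0.15 with scale normalization, where the macrophage median was 1.94. Both lists averaged below the reference on every array, so it is not known that either batch held such cells. This test therefore cannot decide. Quantile normalization, which removes unequal scaling, left the median of the 13 further genes at 1.86 (and that of the 6 genes named for their difference at 4.05).

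Rises at 2 h were larger in batch S8 for 107 of the 130 features that rose with the block (medians 2.80 and 2.44). A higher level at 0 h in batch S7 could account for this if the batches were then close at 2 h. The median difference, S8 minus S7, was -0.061 at 0 h, 0.37 at 1 h and 0.381 at 2 h. At 0 h, 68 of the 130 features were lower in batch S8. For these features the medians do not show a higher level at 0 h in batch S7 that was made up by 2 h. The test cannot decide for other genes, because the block fit favours features that changed alike in both batches. CCL4 (0.62 in batch S7 and -4.52 in batch S8 at 0 h, 4.35 and 3.84 at 2 h) did not pass it. Neither did JUN (3.57 and 0.99 at 0 h, 4.58 and 4.32 at 2 h). A higher level at 0 h therefore stays open as an account. Compressed ratios on the arrays of batch S7 would lower both the SD of the ratios and the SD of the changes. The SD of the ratios, S7 over S8, was 1.09 at 0 h and 1.08 at 2 h, which gives no sign of compression over all spots. The SD of the 2 h change was 0.659 in batch S7 and 0.743 in batch S8. That difference in part restates the larger rises in batch S8, so it cannot decide whether ratios were compressed.

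Of the 7 named genes that fell at 1 h with the block, 5 were ZNF or ZBTB genes, against 2 of 30 that rose and 74 of 2670 tested. A lower level of zinc finger transcripts as a class might account for this. The 69 ZNF and ZBTB genes not taken by the rule for named genes, which still hold 2 of these 5, had median changes of -0.22 in batch S7 (percentile 7.1 of random lists) and -0.30 in batch S8 (percentile 0.16), against -0.13 and -0.11 over all genes. With quantile and scale normalization the medians were -0.09 and -0.09 in batch S7 and -0.24 and -0.20 in batch S8, and at 2 h the percentiles were 70.5 and 3.68, so the batches differ and this stays open.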
